A study of Sepia officinalis with 3 samples.

How the data were processed

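Polyadenylated RNA of the posterior salivary gland, the venom gland of cephalopods, was sequenced from wild-type common cuttlefish (Sepia officinalis). Per the labels, the tissue had been kept in a preservative before extraction, the libraries were stranded and the reads were paired. The series holds 3 libraries, which its design text calls independent replicates, and they form a single group. They are named here libraries 6, 7 and 8 after the replicate numbers in their labels. The labels do not say in so many words that each library came from a different animal, so the spread between these samples may be technical in part. No p-value below extends beyond these samples. No contrast between groups exists, so the comparisons are between libraries, between transcripts and between groups of transcripts within the gland.

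The submitters' processing notes name FastQC, Trim Galore 0.6.6 and kallisto 0.43.0. The transcript names are those of a de novo assembly by Trinity. The assembler version, the quantification settings and any rescaling of the counts are not given in the sources used here. The deposited table gives an estimated count per assembled transcript and library, per the file headers, together with the transcript sequence and its best Swiss-Prot match. The deposited percent identity and E-value describe that match, per the file headers. The estimated counts are not whole numbers, and their totals over the annotated transcripts analysed here were 2512440, 2129197 and 2225171 in libraries 6, 7 and 8. These totals cover part of each library and are not its sequencing depth. The table held 15145 entries with content, and 4012 of its lines were blank and are not analysed here. A transcript with several open reading frames occurs once per frame with its counts repeated, so each transcript was counted once, with the frame of the lowest E-value. This left 14838 transcripts of 9608 Trinity genes with 7253 protein names, of which 14401 transcripts were above 0 in at least 1 library. Other columns of per-sample values numbered 0. No reference genome was used, so no coordinates are given, and names are those of the best match, often in a distant species. The median identity of the matches was 47.9%, so a name marks a protein family and not a proven ortholog.

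The design, fixed before the data were examined, was written for TPM, which scales counts by transcript length and library total, whereas the deposited values are estimated counts. TPM was therefore computed from the estimated counts and the length of the deposited sequence, within the annotated transcripts only, and CPM, which scales counts by the library total alone, were used as the alternative. The design foresaw CPM for the agreement between libraries if only counts were given, so both scales are printed there. TPM favours short assembled fragments, whose length may not be that of the whole mRNA. Log values are log2(TPM + 1).

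Agreement between libraries was described by Pearson's r and Spearman's rho across transcripts above 0 in at least 1 library. Transcripts are not independent replicates, and no p-value was computed. A transcript was called detected at 1 TPM or more. For 27 lists of protein names fixed before the data were examined, the share of TPM per library was summed. The median log2 value of each list with 3 or more members was then placed among the medians of 10000 random lists of the same size, or 2000 in the alternatives. On simulated lists with no shift, 4.50% of 200 reached the top 2.5% of random lists, and 100% did after a shift of 2 on the log2 scale. These simulated lists had a single size and were placed among fewer random lists, so the rate for the real lists may differ. Some list patterns also took in unrelated proteins by part of a word, and the serine protease pattern missed proteins named Duodenase-1 and Collagenase. The serine protease list held 13 cathepsin or endoplasmin transcripts, and the ribosomal list held 95 transcripts of mitochondrial ribosomal proteins. The lists were kept as fixed, and corrected patterns were run as an alternative chosen after seeing the data. The order of 2 lists within a library was tested with an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25.

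Variation between libraries was tested per transcript with a chi-square test of its estimated counts against the libraries' totals scaled by TMM. The p-values were adjusted by Benjamini-Hochberg over transcripts with a mean of 10 counts or more. A transcript was called variable at an adjusted p under 0.05 and 4-fold or more between the highest and the lowest library after adding 1 to each value. The chi-square test covers counting error only and compares these libraries, not conditions. The common biological coefficient of variation came from edgeR with an intercept-only design, for which the counts were rounded to whole numbers. Tested on simulated data for 7004 transcripts, the variable call found 2% of 50 transcripts changed 2-fold and 100% of 50 changed 8-fold, and 0% of 6804 unchanged ones. These simulated counts carried counting error only and no other variation between libraries, so the 0% is not a rate of false calls for the real libraries. In separately simulated counts with added variation, a coefficient of 0.5 was estimated as 0.499. A floor of 3 counts corresponds to 1.19, 1.41 and 1.35 CPM in libraries 6, 7 and 8, so a transcript listed at 0 was below detection at this depth and not shown to be absent. All pairs of libraries were compared for identical values above 0, and 0 were found, so no library was an exact copy of another. A copy rescaled as a whole would escape this check. It would give a correlation near 1 in TPM, where Pearson's r across transcripts did not exceed 0.788.

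Transcripts were called near-identical when blastn found an alignment of 150 bases or more, covering 50% or more of the shorter sequence, at 95% identity or more. By this rule 7408 transcripts had a near-identical partner, and the authors' quantification could divide reads between such partners.

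Named transcripts were chosen by a rule fixed before the data were examined. It takes the 20 annotated transcripts with the highest mean TPM, the 3 most abundant members of each list, and the 10 transcripts with the widest range of log2(TPM + 1) between libraries at a mean TPM of 10 or more. Entries named only as hypothetical, uncharacterized or unnamed would be skipped, and 0 were. A name carried by several transcripts stands for the most abundant one that met the rule. Alternatives covered other pseudocounts, thresholds, scalings (total counts and DESeq2 size factors), sums by name, stricter E-values, lists without their most abundant member, and leaving out each library. Added after seeing the data were sums by Trinity gene, TPM from a length reduced for a fragment of 200 bases, each deposited entry counted, and the corrected list patterns. Computations used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and blastn 2.17.0.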

Results

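RNA of the posterior salivary gland of the common cuttlefish was profiled in 3 replicate libraries of 1 group to describe which transcripts the gland expresses. The estimated counts over the annotated transcripts analysed summed to 2512440 in library 6, 2129197 in library 7 and 2225171 in library 8. Transcripts above 0 numbered 11650, 12270 and 12153 in the same libraries. Values below are means ± SD with n = 3 libraries unless single libraries are given, and a name is that of the best protein match.

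The gland's annotated RNA was led by transcripts of secreted proteases, a phospholipase, a cuttlefish toxin and the protein synthesis machinery. Trypsin, alkaline C, a serine protease that cuts proteins after basic residues, was the most abundant transcript, at 186583 ± 13632 TPM. Chymotrypsin B followed at 113651 ± 58794 TPM and Chymotrypsin BI at 72587 ± 57539 TPM, both serine proteases that cut after large hydrophobic residues. Phospholipase A(2), an enzyme class that releases fatty acids from membrane lipids and occurs in many venoms, stood at 64388 ± 18968 TPM. SE-cephalotoxin, a toxin known from the salivary gland of another cuttlefish, Sepia esculenta, stood at 17814 ± 11677 TPM, and its match had 82.8% identity. It stood at 8753, 13697 and 30991 TPM in libraries 6, 7 and 8, and its Trinity gene summed to 26647 ± 16750 TPM.

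Further secreted proteins among the 20 most abundant named transcripts were Duodenase-1, a serine protease, at 21737 ± 11455 TPM and GLIPR1-like protein 1, a cysteine-rich protein of the CAP superfamily, at 18535 ± 9546 TPM. A disintegrin and metalloproteinase with thrombospondin motifs 9 (ADAMTS9), a family of zinc proteases of the extracellular matrix, reached 8029 ± 4382 TPM. Carboxypeptidase A2, a digestive zinc protease, reached 6140 ± 1018 TPM. A transcript matching Enteropeptidase, the serine protease that activates trypsinogen in vertebrates, reached 5315 ± 2015 TPM. This transcript was near-identical to that of Chymotrypsin B, so the names need not mark separate proteins with separate functions. Summed with its near-identical transcripts, it stood at 186176, 73183 and 100311 TPM in libraries 6, 7 and 8. Chymotrypsin B alone stood at 178939, 64889 and 97124 TPM. Elongation factor 1-alpha 2, which delivers aminoacyl-tRNA to the ribosome, stood at 13971 ± 6376 TPM. Ribosomal subunit proteins took 6 of the 20 places, led by eS25 at 6206 ± 2254 TPM. Protein eva-1 homolog C at 5857 ± 2285 TPM, or 12991 ± 2998 TPM summed over its Trinity gene, and Cold shock protein 1 at 3895 ± 1399 TPM were also among the 20. The transcript matching Collagenase, a trypsin-like protease of a parasitic fly, had a mean of 6592 ± 11325 TPM, nearly all of it from library 8. Together these 20 transcripts held 57.3 ± 9.6% of TPM.

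**Figure D1:**
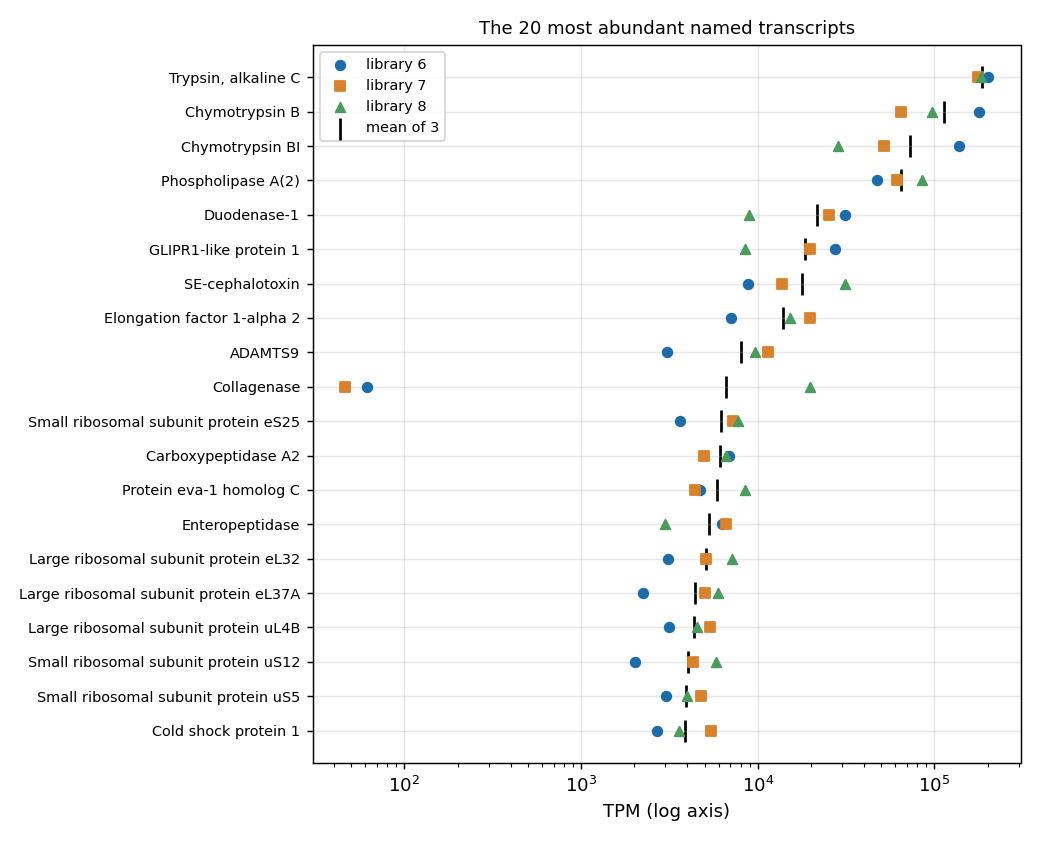
TPM (log axis) of the 20 most abundant named transcripts in libraries 6, 7 and 8, with a black tick for the mean of the 3. Trypsin, alkaline C varied least at the top, from 175259 to 201713 TPM, whereas Collagenase was at 61.6 and 46.1 TPM in libraries 6 and 7 and at 19670 TPM in library 8.

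Several of these leading transcripts were short and weakly matched. The assembled Trypsin, alkaline C transcript had 456 bases, began with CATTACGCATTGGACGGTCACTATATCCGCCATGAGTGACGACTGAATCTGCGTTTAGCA and matched at an E-value of 1.33e-10. The Chymotrypsin B transcript had 309 bases. The SE-cephalotoxin transcript had 2998 bases and began with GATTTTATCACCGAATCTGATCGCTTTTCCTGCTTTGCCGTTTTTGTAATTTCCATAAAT. On the scale without a length correction, Trypsin, alkaline C remained high at 87673 ± 13757 CPM, Chymotrypsin BI stood at 85334 ± 74374 CPM and SE-cephalotoxin at 53349 ± 32271 CPM, above Chymotrypsin B at 37022 ± 22321 CPM. Of the 20 transcripts, 12 were also among the 20 most abundant by CPM.

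Expression was concentrated in few transcripts. The 10 most abundant held 53.3 ± 10.9% of TPM, with 65.7% in library 6, 45.1% in library 7 and 49.2% in library 8. The 100 most abundant held 78.1 ± 5.0%. By CPM these shares were 42.3 ± 8.26% and 65.6 ± 5.36%. At 1 TPM or more, 7294 transcripts were detected in every library, and 9928, 11240 and 11110 in libraries 6, 7 and 8. A threshold of 5 TPM left 3347 transcripts in every library.

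The 3 libraries resembled each other to a similar degree in each pair. Across 14401 transcripts, Pearson's r of log2(TPM + 1) was 0.783 for libraries 6 and 7, 0.788 for 6 and 8, and 0.770 for 7 and 8. Spearman's rho was 0.611, 0.615 and 0.615. On the CPM scale, r was 0.804, 0.813 and 0.795. When the transcripts of a Trinity gene were summed, a choice made after seeing the data, r was 0.874, 0.880 and 0.871 across 9553 genes. These correlations are across transcripts or genes, which are not independent replicates.

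Proteins of the kinds found in venoms made up a large part of the annotated RNA. The 11 venom-type lists, fixed beforehand, held 53.0 ± 11% of TPM, at 65.2%, 44.0% and 49.8% in libraries 6, 7 and 8. Serine proteases held 38.5 ± 12.5% with 100 members above 0, and nearly all of it lay in Trypsin, alkaline C, Chymotrypsin B and Chymotrypsin BI. The fixed list left out Duodenase-1 and Collagenase, and with the corrected patterns it held 41.4 ± 12.9%. Phospholipases and lipases held 6.57 ± 1.92%, almost all in Phospholipase A(2), since the other members left 0.134 ± 0.0766%. Toxin-named proteins held 3.02 ± 1.70% with 17 members above 0. Nearly all of it was SE-cephalotoxin, with Trinity genes of this name at 26647 ± 16750 and 3472 ± 476 TPM. Cysteine-rich venom protein latisemin was at 57.8 ± 39.8 TPM and Venom phosphodiesterase at 12.5 ± 7.59 TPM. The CAP superfamily held 2.57 ± 1.39% with 14 members, nearly all of it in the Trinity gene of GLIPR1-like protein 1 at 25517 ± 13849 TPM.

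Metalloproteases held 1.32 ± 0.377%, led by ADAMTS9, with Angiotensin-converting enzyme, a peptidase that trims peptide hormones, at 713 ± 238 TPM and Neprilysin, which also degrades peptides, at 57.1 ± 32.5 TPM. Carboxypeptidases held 0.635 ± 0.103%, of which all but 0.0215 ± 0.00397% was Carboxypeptidase A2. Protease inhibitors held 0.322 ± 0.195%, led by Serpin B9 at 1488 ± 1212 TPM, and Actinia tenebrosa protease inhibitors stood at 349 ± 144 TPM. Carbohydrases held 0.0622 ± 0.00731%, with Lysosomal alpha-mannosidase, a sugar-trimming enzyme of lysosomes, at 162 ± 12.6 TPM. Lectins held 0.00955 ± 0.00197%, led by the 32 kDa beta-galactoside-binding lectin at 31.8 ± 12.7 TPM. Acetylcholinesterases and carboxylesterases held 0.00708 ± 0.00357%, with Acetylcholinesterase, which breaks down acetylcholine, at 56.6 ± 32 TPM. Tachykinins and neuropeptides held 0.00624 ± 0.00631%, led by Neuropeptide prohormone-4 at 39.5 ± 49.3 TPM, and no transcript matched the monoamine synthesis list, which had 0 members. Without library 7 the tachykinins and neuropeptides held 0.0026%, and without library 8 the protease inhibitors held 0.21%.

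By median member, 3 venom-type lists stood in the top 2.5% of random lists of the same size. These were the serine proteases at the 100th percentile, the CAP superfamily at 99.8 and the toxin-named proteins at 99.5. With CPM the percentiles were 77.1, 96.3 and 96.3, and with transcripts summed by name they were 99.1, 80.5 and 40.3. The names GLIPR1-like protein 1 and SE-cephalotoxin were each carried by 6 further transcripts, so the medians of their lists rest in part on repeated names. Leaving out library 7 gave 95.9 for the CAP superfamily and 95.1 for the toxin-named proteins. Leaving out library 6 put the toxin-named proteins at 97.45, too near the threshold to tell its side with 2000 random lists. Protease inhibitors stood at percentile 1.33, but at 51.1 among transcripts with a mean TPM of 1 or more, 15.6 with CPM and 10.5 without library 8, so their low position was not kept. With matches limited to an E-value of 1e-20 or less, the venom-type lists held 14.8 ± 5.51% of TPM, the serine proteases 8.01 ± 5.75%, the metalloproteases 0.112 ± 0.0192% and the phospholipases and lipases 0.0447 ± 0.0068%, as the leading Phospholipase A(2) matched at 4.29e-09. By CPM the serine proteases held 22.0 ± 10.8% and the toxin-named proteins 8.35 ± 4.52%, while the CAP superfamily held 4.05 ± 2.45%, phospholipases and lipases 5.36 ± 1.22%, carboxypeptidases 1.05 ± 0.219% and metalloproteases 0.805 ± 0.133%. Carbohydrases then held 0.147 ± 0.00306%, protease inhibitors 0.274 ± 0.128%, lectins 0.0191 ± 0.00307%, acetylcholinesterases and carboxylesterases 0.0157 ± 0.0072% and tachykinins and neuropeptides 0.0104 ± 0.00986%.

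The order of the venom-type lists was largely shared by the 3 libraries. Serine proteases exceeded phospholipases and lipases in 3 of 3 libraries, by 2.54 ± 0.80 on the log2 scale, and toxin-named proteins by 3.77 ± 1.13. Of the 55 pairs of lists, 51 had one order in every library. If either order were equally likely in each library, 13.8 would be expected. Many lists differed far in size, so exceeding this number says little. The exact sign-flip permutation test cannot go below p = 0.25 with n = 3, and the smallest adjusted p over the 55 pairs was 0.270, so no order passed a test. Phospholipases and lipases exceeded toxin-named proteins by 1.23 ± 0.37 in TPM, but the order was turned in CPM, with a log2 ratio of -0.53. The CAP superfamily exceeded toxin-named proteins in libraries 6 and 7 and was below them in library 8, where the log2 ratio was -2.21.

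Outside the venom-type lists, the protein synthesis and secretion machinery was prominent. Ribosomal proteins held 17.3 ± 5.58% of TPM with 276 members above 0, translation factors 3.11 ± 1.11%, and stress and chaperone proteins 1.33 ± 0.390%, or 0.907 ± 0.252% with the corrected patterns. Secretory pathway proteins, which fold and export new proteins, held 1.17 ± 0.310%, led by Protein disulfide-isomerase at 1850 ± 669 TPM and Translocon-associated protein subunit delta at 1256 ± 519 TPM. Oxidative phosphorylation proteins held 0.990 ± 0.205%, with ATP synthase subunit beta at 736 ± 185 TPM. Glutathione and redox proteins held 0.300 ± 0.0541%, with Glutathione S-transferase Mu 4 at 486 ± 181 TPM. By CPM ribosomal proteins held 13.4 ± 3.59%, translation factors 4.86 ± 1.49%, secretory pathway proteins 1.93 ± 0.431%, stress and chaperone proteins 1.64 ± 0.532%, oxidative phosphorylation proteins 1.04 ± 0.149% and glutathione and redox proteins 0.338 ± 0.0359%. These 6 lists also stood in the top 2.5% of random lists by median member, at percentiles from 99.98 to 100.

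Transcripts of the lists for other tissues were found in all 3 libraries, but their names alone do not show the tissue they came from. Muscle proteins held 0.492 ± 0.0888% of TPM, led by Arginine kinase Oct f 2, the phosphagen kinase of molluscan muscle, at 893 ± 149 TPM, with the mantle muscle Myosin regulatory light chain LC-2 at 445 ± 108 TPM. The neuron list held 0.116 ± 0.0217%, and 0.0640 ± 0.00911% after proteins not specific to neurons were removed in the corrected list. Connective tissue proteins held 0.0859 ± 0.0238%, led by Collagen alpha-2(I) chain at 140 ± 94.8 TPM. Blood and haemocyte proteins held 0.0324 ± 0.00413%, led by Ferritin at 73.1 ± 35.8 TPM. Skin, eye and ink proteins held 0.0307 ± 0.0035%, most of it a Melanotransferrin match at 164 ± 9.8 TPM, an iron-binding protein that the corrected list leaves out. Their median was at percentile 97.4 as fixed and 82.2 as corrected. The corrected skin, eye and ink list held 0.00796 ± 0.00155% and the corrected blood and haemocyte list 0.0222 ± 0.00192%. By CPM muscle proteins held 1.30 ± 0.199%, connective tissue proteins 0.295 ± 0.11%, neurons 0.233 ± 0.0209%, skin, eye and ink proteins 0.0659 ± 0.00269% and blood and haemocyte proteins 0.0294 ± 0.000668%. The muscle list stood at percentile 36.6 in TPM, 99.7 in CPM and 100 with transcripts summed by name.

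Mucins and mucus proteins held 0.0321 ± 0.00771%, led by Sialomucin core protein 24 at 49.6 ± 52.6 TPM. This transcript stood at 32.5, 108.7 and 7.72 TPM in libraries 6, 7 and 8, and at 42.4, 137 and 172 TPM summed with its near-identical transcripts. Antimicrobial and innate immune proteins held 0.0142 ± 0.00302%, led by Lipopolysaccharide-binding protein at 73.5 ± 10.7 TPM. Cell cycle proteins held 0.0421 ± 0.0145%, with Proliferating cell nuclear antigen, the sliding clamp of DNA replication, at 55.0 ± 29 TPM. Transposable element proteins held 0.0512 ± 0.0164% over 186 members above 0, 0.739 ± 0.422% when each deposited entry was counted, 0.0816 ± 0.0238% by CPM, and 0.0212 ± 0.0068% at an E-value of 1e-20 or less. Counting each entry adds further reading frames with the full counts of their transcript. The share of 0.739% thus comes mostly from transcripts otherwise counted under other names. By CPM mucins and mucus proteins held 0.057 ± 0.0099%, antimicrobial and innate immune proteins 0.0314 ± 0.0066% and cell cycle proteins 0.0735 ± 0.0235%. With the corrected patterns the mucins and mucus list held 0.0187 ± 0.00879% and the cell cycle list 0.0245 ± 0.00711%, and mucins and mucus proteins held 0.0114 ± 0.0024% at an E-value of 1e-20 or less. By median member the cell cycle list stood at percentile 2.27 and the transposable elements at the lowest position reached, below all random lists. Neither position held under each alternative, since the cell cycle list stood at percentile 29.1 without library 8, and the transposable elements reached the upper 2.5% of random lists when transcripts were summed by name.

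**Figure D2:**
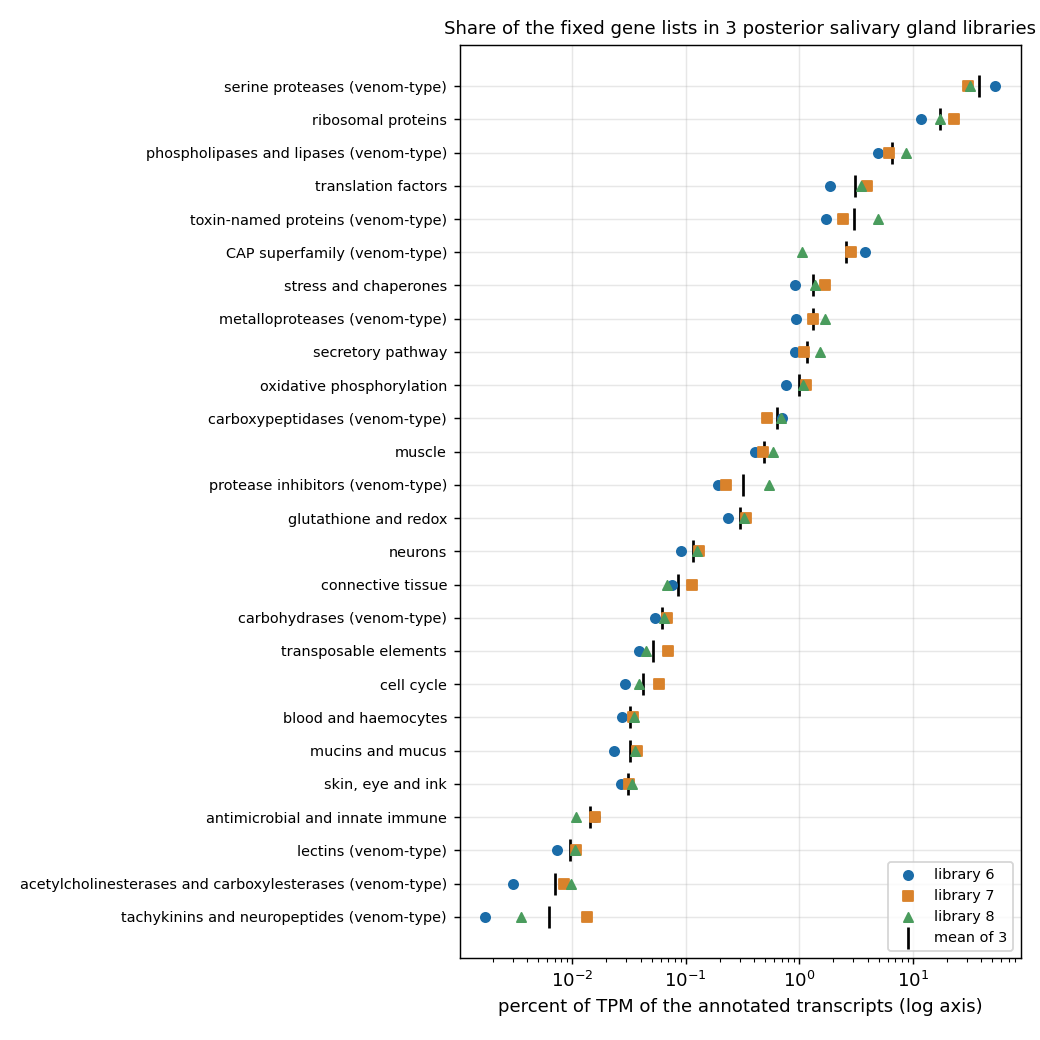
Percent of TPM (log axis) held by each fixed list with 3 or more members above 0, in libraries 6, 7 and 8, with a black tick for the mean of the 3. Serine proteases lead at 52.9%, 30.4% and 32.1%, followed by ribosomal proteins at 11.7%, 22.9% and 17.3%.

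Transcripts differed widely between the 3 libraries. Of 7004 transcripts tested, 4812 (68.7%) differed by more than counting error in the chi-square test, and 1804 of them did so by 4-fold or more. The highest library was 6 for 526 of these, 7 for 679 and 8 for 599. With total-count scaling the split was 362, 847 and 682. The common biological coefficient of variation was 0.774. Summed by Trinity gene, 347 of 4848 genes differed by 4-fold or more and the coefficient was 0.384. Any 2 of the 3 libraries gave fewer transcripts, 1177 without library 6, 986 without library 7 and 1081 without library 8, as the comparison then rests on fewer values.

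The widest single range not shared with a near-identical transcript belonged to Collagenase, at 83.8, 46.5 and 20410 estimated counts in libraries 6, 7 and 8. Its 481-base transcript began with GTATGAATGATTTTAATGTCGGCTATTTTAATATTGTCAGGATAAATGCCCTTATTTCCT, and its range of 8.71 on the log2(TPM + 1) scale was 7.47 after summing with its near-identical transcripts. Probable peptidylglycine alpha-hydroxylating monooxygenase 1, an enzyme that matures amidated peptides, ranged over 8.45 alone and 3.90 after summing, highest in library 8. P-selectin, a name of vertebrate cell adhesion proteins, ranged over 8.29 and 2.23, highest in library 7. The other 7 of the 10 transcripts with the widest range fell below 4-fold after summing with near-identical transcripts, whereas 4 of the 10 stayed at 4-fold or more when summed by Trinity gene. Among them were the ribosomal proteins eL14, uS3, eL29 and uL3, with ranges of 11.18, 10.60, 8.92 and 7.53 alone and between 0.97 and 1.49 after summing. Nucleolin ranged over 9.01 and 1.76, the V-type proton ATPase proteolipid subunit c over 7.83 and 0.78, and a second Phospholipase A(2) transcript over 7.40 and 0.83. That last sum consists mostly of the more abundant Phospholipase A(2), and within its own Trinity gene the second transcript kept a range of 6.99, at 1328, 9.49 and 1330 TPM in libraries 6, 7 and 8. In 7 of the 10, at least 1 library was below the floor of 3 counts.

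**Figure D3:**
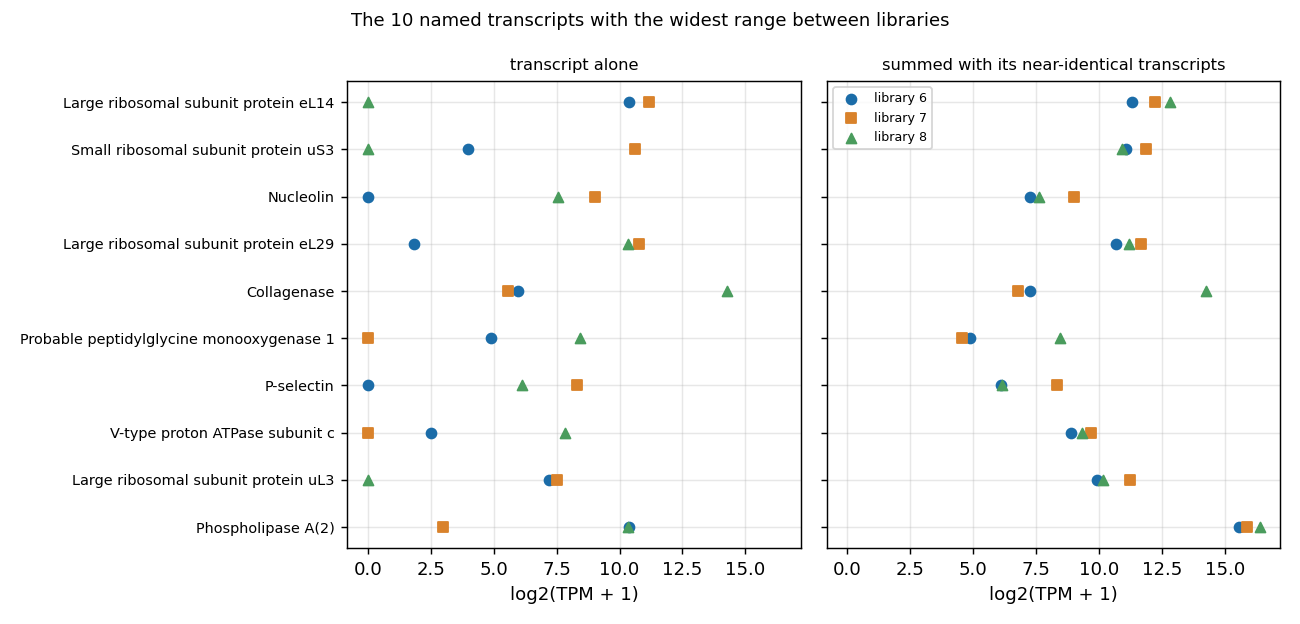
Values of log2(TPM + 1) in libraries 6, 7 and 8 for the 10 named transcripts with the widest range between libraries, each alone (left) and summed with its near-identical transcripts (right). After this sum 3 of the 10 keep a range of 4-fold or more, against 4 when summed by Trinity gene, and Collagenase keeps 7.47.

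The venom-type lists varied in different directions between the libraries. The CAP superfamily ranged 3.57-fold, from 1.07% of TPM in library 8 to 3.80% in library 6, whereas toxin-named proteins ranged 2.90-fold, from 1.70% in library 6 to 4.94% in library 8. These ranges are mostly those of GLIPR1-like protein 1 and of SE-cephalotoxin, which made up nearly all of the respective list. Protease inhibitors ranged 2.82-fold and were highest in library 8, where Serpin B9 stood at 2885 TPM against 727 and 851 in libraries 6 and 7. Tachykinins and neuropeptides ranged 7.85-fold and were highest in library 7, with Neuropeptide prohormone-4 at 3.54, 95.7 and 19.3 TPM in libraries 6, 7 and 8. Acetylcholinesterases and carboxylesterases ranged 3.21-fold and translation factors 2.14-fold. These 6 of 26 lists reached a 2-fold range in TPM. In CPM serine proteases at 2.28-fold and connective tissue at 2.18-fold also did, while translation factors at 1.90-fold did not.

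Serine proteases ranged 1.74-fold in TPM and 2.28-fold in CPM, highest in library 6 on both scales. Within the list, Chymotrypsin BI stood at 137627, 51822 and 28313 TPM in libraries 6, 7 and 8, while Trypsin, alkaline C differed by 0.20 on the log2 scale. Muscle proteins ranged 1.43-fold, neurons 1.44-fold, blood and haemocytes 1.27-fold, connective tissue 1.65-fold, and stress and chaperone proteins 1.84-fold. Ribosomal proteins ranged 1.95-fold and were lowest in library 6, where the 10 most abundant transcripts took the largest share. No test between animals exists for these ranges in a single group of 3.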

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

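The tests of GC content and of an even rate between libraries were chosen after the results they measure had been seen. Some transcripts match proteins of other organisms at 95% identity or more, a signal outside the comparisons of the report, and each sum below lies above the 3 counts that a count of 0 allows. Transcripts matching variable segments of human T cell receptors and antibodies summed to 1349.4 estimated counts over the 3 libraries, in 96 transcripts, at 167, 211 and 216 CPM in libraries 6, 7 and 8. Transcripts matching Campylobacter, a genus of bacteria, summed to 217.1, in 50 transcripts. They held 13.1 counts in library 6 (95% Poisson interval 6.96 to 22.3), 20.2 in library 7 (12.4 to 31.1) and 184 in library 8 (158 to 212), intervals that cover counting error only. Transcripts matching mouse leukaemia viruses summed to 72.9, in 9 transcripts, with 24.1, 20.1 and 28.8 counts in libraries 6, 7 and 8.

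Conserved cuttlefish genes were weighed as the source of the human and Campylobacter matches and argued against by GC content, within a limit of length. The median was 52.4% for the human matches and 36.8% for the Campylobacter matches, where 95% of 10000 random sets of as many transcripts lay between 38.5% and 40.4%, and between 38.1% and 40.8%. The random sets were not matched on length. The median length was 492 bases for the human and 450 for the Campylobacter matches, against 1237 for all transcripts. A difference in GC content tied to length was therefore not separated. Carry-over of Campylobacter material at one even rate into each library is argued against by its 15.91-fold range in CPM. RNA from handling, from other sequencing libraries or from bacteria in or on the gland stays open as a candidate source, and these were not tested against each other. No biological explanation was tested, since the design gives no groups.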

How the results depend on the processing

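Sums by Trinity gene, the reduced length, the corrected patterns and the count of each deposited entry were chosen after seeing the data, and the other alternatives before. The cause of a change was not tested unless the construction shows it. For library pairs 6 and 7, 6 and 8, and 7 and 8, r was 0.598, 0.599 and 0.584 with a pseudocount of 0.1, 0.772, 0.778 and 0.749 at a mean TPM of 1 or more, 0.804, 0.813 and 0.795 in CPM, and 0.874, 0.880 and 0.871 by Trinity gene. A threshold of 5 TPM left 3347 transcripts. In CPM the 10 and 100 most abundant transcripts held 42.3% and 65.6%, and serine proteases 22.0%. Apart from serine proteases, CPM moved 17 list shares by more than their SD between libraries, leaving out the most abundant member 13, the reduced length 9, the corrected patterns 8, the stricter E-value 6 and the count of each deposited entry 1. Without their most abundant members, the venom-type lists held 22.7% and serine proteases 19.8%, and at an E-value of 1e-20 or less 14.8% and 8.01%, as fewer transcripts counted. The number of variable transcripts was 3757 without the count filter, 407 at a mean of 50 counts or more, 3515 at 2-fold, 347 by Trinity gene, and 986 to 1177 without 1 library. The coefficient of variation was 0.864, 0.597 and 0.384 for no filter, 50 counts and Trinity genes. Between neighbours in the order of the lists, 10 log2 ratios turned. In CPM, phospholipases to toxin-named proteins gave -0.53 and metalloproteases to carboxypeptidases -0.37. Without the most abundant members, phospholipases to toxin-named proteins gave -3.37, carboxypeptidases to protease inhibitors -2.94, and acetylcholinesterases to neuropeptides -0.57. By number of members, CAP superfamily to metalloproteases gave -2.10, carboxypeptidases to protease inhibitors -1.77, protease inhibitors to carbohydrases -0.0687, and acetylcholinesterases to neuropeptides -0.58. Toxin-named proteins to the CAP superfamily ranged from -0.69 without library 8 to 0.99 without library 6. Of 381 alternatives for single lists, ratios of neighbours and transcripts, these 10 included, 314 stayed within the bounds used for them and 57 moved. Serine proteases stayed the first of the venom-type lists in TPM and CPM, without their most abundant member, by number of members and without each library. At an E-value of 1e-20 or less they were first on the mean, at 8.01% against 3.02% for toxin-named proteins. In library 8, however, they then held 3.55% against 4.94% for toxin-named proteins. At this depth 3 counts correspond to 1.19 to 1.41 CPM, which limits what is detected. Summing by name leaves a list's share as it is, so for the lists it was applied to percentiles only.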

Other observations

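The genes in the next 2 paragraphs, the comparisons with unrelated partners and the comparison of Trinity genes with random groups were chosen after the values had been seen, while the sums over near-identical transcripts and the test of the ribosomal share were set before their results. Some heat shock genes, whose products help proteins to fold, had their highest value in library 7, with no test. Summed by Trinity gene, Heat shock protein HSP 90-alpha held 1202, 10919 and 1092 estimated counts in libraries 6, 7 and 8. A Heat shock 70 kDa protein gene stood at 391, 1764 and 388 TPM, and Heat shock protein 70 B2 at 1.71, 33.0 and 2.08 TPM. The constitutive Heat shock cognate 71 kDa protein stood at 209, 547 and 421 TPM. Of 15 chaperone and co-chaperone genes at a mean of 10 TPM or more, 11 were highest in library 7 in TPM and 9 after TMM scaling, where 51.0% and 38.8% of all 2938 genes at this level were. The fixed stress and chaperone list, of 57 genes, was near these shares. In it 28 genes were highest in library 7 in TPM and 23 after TMM scaling, against 28 and 22 in library 8. Heat shock 70 kDa protein 12A, Heat shock factor-binding protein 1, DnaJ homolog subfamily B member 12 and DnaJ homolog subfamily B member 9 were highest in library 8 in TPM, the last, a co-chaperone of the endoplasmic reticulum, at 33.8, 10.4 and 96.2 TPM.

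The library in which most genes of a list were highest was not tested. Among ribosomal protein genes at a mean of 10 TPM or more, 97 of 129 were highest in library 7 in TPM and 85 after TMM scaling. Among secretory pathway genes 26 of 37 were highest in library 8 in TPM and 19 after TMM scaling, when 15 were highest in library 6 against 2 in TPM. Of all 2938 genes 44.7% and 35.9% were highest in library 8 on these scales, and 4.29% and 25.2% in library 6. The shift toward library 6 after TMM scaling was thus seen across all genes. Of 24 serine protease genes, 10 differed 4-fold or more between libraries in TPM, against 182 of all 2938 genes, with no test. The carbohydrases had 4 of 12, blood and haemocytes 3 of 8, connective tissue 3 of 13 and ribosomal proteins 3 of 129. Chymotrypsin-like protease CTRL-1 held 85.3 estimated counts in library 6 and was below 3 counts in the others, and a Coagulation factor XI match, also of the trypsin family, held 12.1, 317 and 7.90 counts in libraries 6, 7 and 8. Of 2 genes matching Chitotriosidase-1, a chitin-degrading enzyme, one held 214, 0 and 2.01 counts and the other 22.9, 293 and 57.4.

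Of the 1804 transcripts that differed 4-fold or more, 87.4% had a near-identical transcript, against 59.6% of the transcripts tested. After summing with these, 23.1% stayed at 4-fold or more, but sums with unrelated partners of the same abundance left 26.2% to 29.8% in 50 draws, so this value alone says little. The near-identical transcripts were together higher in the library where the transcript was lowest in 64.2% of cases, against at most 52.6% with unrelated partners, and 350 Trinity genes (347 with scale factors of their own) differed 4-fold or more with the transcripts' scale factors, against 960 to 1040 random groups of the same sizes. Reads of one gene divided between near-identical assembled forms may thus account for part of the pattern. Whether the forms are alleles, splice variants or gene copies was not tested, nor was any biological explanation, and Collagenase kept a log2 range of 7.47 after the sum.

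Ribosomal proteins held a lower share of TPM in library 6, at 11.7% against 22.9% and 17.3%, where the 10 most abundant transcripts took 65.7%. That share counts the 10 most abundant transcripts of library 6 itself. The 10 left out for the test were not exactly each library's own 10 and took slightly less of each library. With them left out, the ribosomal shares were 33.2%, 41.6% and 33.3%, and the range was 1.254-fold instead of 1.95-fold. This range lies just above the bound set beforehand for the share of the 10 transcripts as the cause, and below the 1.5 set for excluding it. On which side of the lower bound it falls may depend on which 10 are left out. Library 6 was then level with library 8, while library 7 stayed above both, so the share of the 10 most abundant transcripts may explain the lower value against library 8 and leaves library 7 open.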
